A study of Homo sapiens with 6 samples.

How the data were processed

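Total RNA from MV411 cells was extracted with chloroform, poly(A) RNA was purified from 3 micrograms with oligo-dT beads, and libraries made with random priming were amplified over 15 PCR cycles and read as pairs of 150 bases on an Illumina instrument, per the labels' protocols. The protocols used here do not state that strand was kept, so a gene and its antisense partner cannot be told apart. The dose of corilagin is not given in the sources used here. Read trimming with fastp 0.22.0, alignment with HISAT2 2.1.0 to GRCh38, counting with HTSeq 0.9.1 and DESeq 1.38.3 are named in the submitters' processing notes, without their settings. The authors deposited 1 table of FPKM for 20036 Ensembl gene identifiers in 6 libraries, and the column names match the library names in the labels. FPKM divides a library's fragments by gene length and library total, so a few highly expressed genes can shift all others, and overlapping genes, close paralogs and pseudogenes can share or lose reads.

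The FPKM values were whole multiples of the value of 1 fragment. From these steps the number of fragments per gene was recovered for all 15921 genes above 0 in any library, with 100.0% of values within 0.01 of a whole number. The search accepted only whole multiples, so that share follows from the method and is no separate check. The totals, themselves inferred from the FPKM values, were 17776956 to 21640689 fragments per library. The fragments recovered in listed genes summed to 99.98 to 100.02% of these totals. They exceeded the totals in the corilagin libraries, so the totals are approximate. On simulated libraries of 3000 genes, built as whole multiples in the same way, 100.0% of values were recovered exactly. Of the deposited genes, 4115 were at 0 in all libraries. Symbols were matched for 20011 identifiers, 19852 were in GENCODE release 29 (GRCh38), from which coordinates and transcript GC content were taken, and 19739 were protein-coding there. In the gene lists, 15 symbols, some of them older synonyms of matched members, had no match. No pair of libraries was identical, and the counts of the closest pair differed by more than sampling noise (chi-square of 2.61 per gene). Intervals on shares of fragments cover counting error only, since PCR copies were not told apart.

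The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, 2-sided) on log2(FPKM + 1) over all 6 libraries, without covariates, for the 9868 genes with a mean FPKM of at least 1, with Benjamini-Hochberg adjustment over those genes and a threshold of 0.05. A fold change on that scale understates changes of genes near 1 FPKM, so ratios of mean FPKM are given as folds, and log2 values are from the fit. Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the 36 lists that had at least 5 tested members. The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. Named genes were TXNIP and GSDME, the 12 largest rises and the 12 largest falls among protein-coding genes past the threshold with a mean of at least 5 FPKM and no overlap between groups, up to 2 rises and 2 falls per list, and the other gasdermins with TXN, TXNRD1, CASP1, CASP8 and CASP9. Further genes named beside a count of 5 or fewer were chosen after their values were seen, and SLC11A2 after those of TFRC but before its own. Results for 2 further genes under these rules are not reported here.

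On simulated FPKM for the comparison of corilagin with DMSO (9860 genes tested), limma recovered 82 of 100 genes changed 1.5-fold and 99 of 100 changed 2-fold and called 13 unchanged genes. With a simulated GC trend in DMSO replicates 1 and 2 (9866 genes tested), it recovered 49 and 84 of 100 with 58 false calls, and after the trend was removed 86 and 98 of 100 with 14 false calls. The simulated trend was linear in GC content and the only fault added, so these counts do not cover other differences between the real libraries. In the same simulation without the trend, camera called the list that had been raised, and 1 of 100 random lists fell under the threshold of 0.05. Genes were simulated independently, so this does not show how camera behaves on lists whose members vary together. The estimated correlation of the real lists reached 0.947 (mitochondrially encoded mRNAs).

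The GC trend was removed by fitting, in each library, a natural spline with 5 degrees of freedom of the deviation from the gene mean on transcript GC content (9859 of the tested genes have one), and in a further version a spline of transcript length with 4 degrees of freedom. It also takes out any true difference between groups that follows GC content. These versions, the fits without the third or the first 2 DMSO libraries and limma-voom on the recovered fragments were added after the data were seen. Alternatives fixed in advance were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, rescaling to equal sums per library, median-of-ratios scaling, quantile normalization, limma without a trend, the replicate number as a block, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9. No library was left out of the main results, and no column of the table was unused.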

Results

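Gene expression was measured by RNA-seq in MV411 cells, an established human acute myeloid leukaemia line of monocytic type that carries a KMT2A fusion and an internal tandem duplication in FLT3. Cells were exposed for 48 h to corilagin, a plant polyphenol of the ellagitannin class, or to DMSO as the control, with 3 libraries per group. Expression was given as FPKM (fragments per kilobase of gene, scaled by the library total) for 20036 genes. The whole fragments recovered from these values put the depth at 21640689, 19562738 and 18299789 fragments in corilagin replicates 1, 2 and 3, and at 19657766, 20063657 and 17776956 fragments in the DMSO replicates. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

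The comparison of corilagin with DMSO asks which transcripts changed with treatment. The series title places TXNIP and GSDME in a pathway leading to pyroptosis, a lytic form of cell death executed by gasdermins. After corilagin, the cells carried more mRNA of the cell cycle inhibitor CDKN1A, of the transferrin receptor TFRC, of the stress-induced transcription factor ATF3 and of cholesterol synthesis enzymes (17 of 23 members of their list). They carried less mRNA of MYC, of ribosome biogenesis factors (29 of 39 members of the MYC and ribosome biogenesis list) and of the granule proteases ELANE and PRTN3. Both lists were called by camera with a preset correlation and neither with an estimated one (adjusted p = 0.106 for each). Among genes with a mean of at least 5 FPKM, CDKN1A rose the most, from 5.17 ± 1.44 to 38.1 ± 2.22 FPKM (SD, n = 3 per group), a 7.38-fold difference. Among the same genes ELANE had the largest fall on the log2(FPKM + 1) scale, to 0.286 of the DMSO level, from 83.7 ± 12.1 to 23.9 ± 0.480 FPKM. TXNIP rose, and GSDME lay close to 1 FPKM in both groups.

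TXNIP, an inhibitor of thioredoxin and a regulator of glucose uptake (ENSG00000265972, GRCh38 chromosome 1, 145992435 to 145996600, minus strand), was at 70.6 ± 2.14 FPKM after corilagin and 31.3 ± 3.43 FPKM in DMSO, a 2.25-fold rise seen in all 3 corilagin libraries against every DMSO library. Its log2 fold change was 1.15 (SE 0.0965) with an adjusted p of 0.00189 in limma. With the GC trend between libraries removed, the TXNIP difference was 1.02 (adjusted p = 0.000322). GSDME, a pore-forming gasdermin (ENSG00000105928, chromosome 7, 24698351 to 24758113, minus strand), was at 0.832 ± 0.0524 FPKM after corilagin and 0.979 ± 0.0401 FPKM in DMSO, below the filter of 1 FPKM. In the limma fit without that filter its log2 difference was -0.11 (SE 0.0497) with an adjusted p of 0.174, from 127 to 175 fragments per library. The exact 2-sided permutation test gave p = 0.1 for both genes, the smallest value that 3 against 3 libraries allow.

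**Figure D1:**
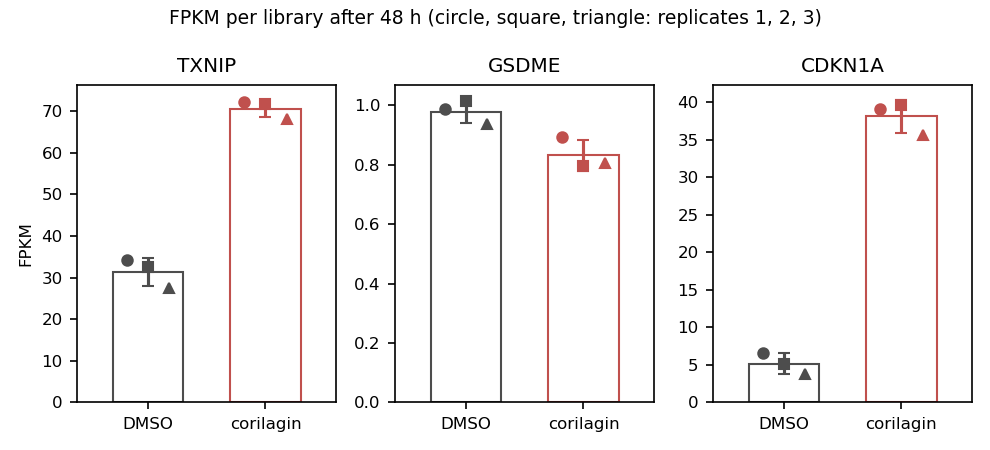
FPKM of TXNIP, GSDME and CDKN1A after 48 h in DMSO (grey) and corilagin (red), with each library as a symbol, the group mean as a bar and the SD as the error bar (n = 3). TXNIP lies at means of 31.3 FPKM in DMSO and 70.6 FPKM after corilagin, GSDME at 0.979 and 0.832 FPKM, and CDKN1A at 5.17 and 38.1 FPKM.

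Other genes of cell death moved in both directions. GSDMD, the gasdermin cleaved by inflammatory caspases, fell from 11.8 ± 1.17 to 8.73 ± 0.488 FPKM (log2 fold change -0.39, limma adjusted p = 0.0304), and its change shrank to -0.15 with the GC trend removed (adjusted p = 0.0461). GSDMB was at 3.29 ± 0.422 FPKM after corilagin and 3.31 ± 0.284 FPKM in DMSO (adjusted p = 0.950), and GSDMA and GSDMC had 6 fragments or fewer in every library. The caspases CASP1, CASP8 and CASP9 did not pass, with adjusted p of 0.0951, 0.0749 and 0.254. In the list of pyroptosis and inflammasome genes, 6 of 17 tested members were higher, 3 lower and 8 did not pass (7 higher and 3 lower adjusted over the list alone), and the list was not called (camera adjusted p = 0.675; 6 higher and 3 lower with the GC trend removed). IL1B, a cytokine matured by the inflammasome, rose 1.72-fold, and PYCARD, the inflammasome adaptor, fell to 0.705 of its DMSO level. Among BCL2 family and apoptosis genes, 8 of 28 were higher and 2 lower (8 and 2 adjusted over the list alone), and the list was not called (camera adjusted p = 0.454). Once the GC trend was removed, 7 of these genes were higher and 6 lower. BCL2L11, a pro-apoptotic BH3-only protein, rose 1.68-fold, whereas BIK and HTRA2 fell to 0.666 and 0.690 of DMSO. BCL2A1 rose 2.35-fold from 0.832 FPKM, a call that ended with the GC trend removed (adjusted p = 0.276).

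In the thioredoxin and TXNIP list, 3 of 15 members were higher (ARRDC3, TXNIP and ARRDC4), 2 were lower (PRDX2 and ARRDC1) and 10 did not pass. The counts were the same adjusted over the list alone, and 3 higher and 5 lower with the GC trend removed. ARRDC3 rose 4.64-fold, from 0.686 ± 0.208 to 3.18 ± 0.211 FPKM. The list was not called (camera adjusted p = 0.680), and its median of -0.13 and mean of 0.05 differ in sign. Thioredoxin itself, TXN, was at 152 ± 5.43 FPKM after corilagin and 138 ± 18.2 FPKM in DMSO (adjusted p = 0.298). The sign of the TXN difference turned with the GC trend removed (log2 difference -0.33, adjusted p = 0.0401). TXNRD1 did not pass (adjusted p = 0.152).

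Across the transcriptome, limma called 1171 of 9868 tested genes higher and 1331 lower after corilagin at an adjusted p under 0.05, of which 76 and 42 had an absolute log2 fold change of at least 1. All values of one group lay above all values of the other for 4762 genes, or 48.3%, against 10% by chance. The libraries also differed by the GC content of the transcripts. In the eighth of genes with the lowest GC (32.0 to 40.2%), DMSO replicates 1 and 2 lay at -0.52 and -0.44 log2 units from the gene mean, whereas DMSO replicate 3 lay at 0.25 and the corilagin libraries at 0.22 to 0.27. In the eighth with the highest GC (60.9 to 76.8%), the first 2 DMSO libraries lay at 0.24 and 0.22, DMSO replicate 3 at -0.09 and the corilagin libraries at -0.09 to -0.16. Across 9859 genes, which are not independent replicates, GC content had a Spearman correlation of -0.850 with the difference of DMSO replicate 3 from the other DMSO libraries, and of -0.004 with the difference of corilagin from DMSO replicate 3. In the lowest eighth 205 genes were called higher and 4 lower, and in the highest eighth 44 and 347. After each library's GC trend was removed, a correction chosen after seeing the data, 2200 genes were higher and 2348 lower, and 935 of the 1171 rises and 1227 of the 1331 falls kept their call. Without DMSO replicate 3, 4030 genes were higher and 3597 lower, and without any one corilagin library 131 to 151 were higher and 176 to 203 lower. The fit without DMSO replicate 3 aligns the GC difference between libraries with treatment. GC content had a Spearman correlation of -0.732 with the difference of corilagin from DMSO replicates 1 and 2. Genes or lists that gain or lose a call in that fit therefore cannot be assigned to treatment alone. Rescaling FPKM to equal sums per library raised the median log2 difference of all tested genes from 0.035 to 0.155, and 1558 higher against 1051 lower calls (59.7% higher) stood beside the 46.8% of the values as deposited. Other scalings moved the balance the opposite way, to 957 higher and 1518 lower (38.7%) with median-of-ratios scaling and 1028 and 1498 (40.7%) with quantile normalization.

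**Figure D2:**
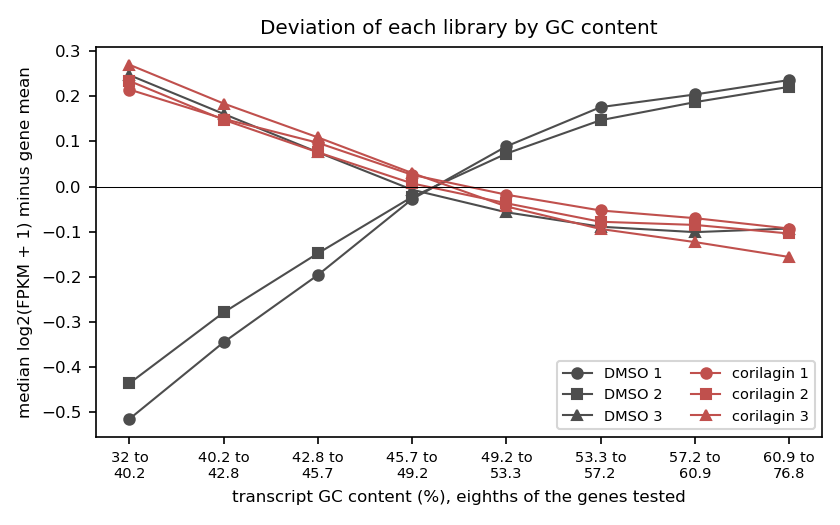
Median deviation of each library from the gene mean, in log2(FPKM + 1), for genes in eighths of transcript GC content (%), with DMSO libraries in grey and corilagin libraries in red. DMSO replicates 1 and 2 run from -0.52 and -0.44 in the lowest eighth to 0.24 and 0.22 in the highest, and DMSO replicate 3 runs with the corilagin libraries from 0.25 to -0.09.

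The 12 largest rises among well expressed genes were CDKN1A, H2AC6, TFRC, LACC1, ATF3, SLC7A11, RESF1, OSBPL8, HMGCS1, CD86, SC5D and CHAC1. TFRC, which imports transferrin-bound iron, rose 3.97-fold from 21.4 ± 3.60 to 84.8 ± 1.97 FPKM (log2 fold change 1.95, SE 0.118, limma adjusted p = 0.00101). ATF3 rose 4.52-fold, SLC7A11, the cystine transporter subunit, 4.09-fold, and CHAC1, a glutathione-degrading enzyme, 3.0-fold. The T-cell costimulatory ligand CD86 rose 2.95-fold. H2AC6, a histone gene with near-identical copies whose reads are hard to assign, was 4.60-fold higher. LACC1, an enzyme of inflammatory macrophages, was 3.65-fold higher, and its call was lost without corilagin replicate 3. SLC7A11 lay at 3.59 FPKM in DMSO replicate 3, against 1.52 and 1.72 FPKM in DMSO replicates 1 and 2. With the GC trend removed, log2 values went from 1.70 to 1.12 for SLC7A11, from 1.81 to 1.34 for LACC1 and from 1.35 to 0.83 for SC5D. Those of the other rises also shrank, except CDKN1A, ATF3 and CHAC1, which grew. RESF1 and OSBPL8 were 2.55-fold and 2.41-fold higher, or 5.0-fold and 4.34-fold without DMSO replicate 3, since that library lay at 34.1 and 25.1 FPKM, near the corilagin means of 44.1 and 32.0 FPKM, and both calls were lost without any one library other than DMSO replicate 3.

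Among the 12 largest falls were ELANE, PRTN3 and PRSS57, serine proteases of myeloid granules, the metallothionein MT1G, the proline synthesis enzyme ALDH18A1, the HSP90 co-chaperone FKBP4 and the mitochondrial ribosomal protein MRPS26. The others were HPDL, PPP1R27, B3GNT7, PODXL2 and MFSD3. PRTN3 fell from 133 ± 21.1 to 47.2 ± 2.0 FPKM, ALDH18A1 from 31.4 ± 3.56 to 10.8 ± 0.531 FPKM, and HPDL, an enzyme of coenzyme Q synthesis, from 8.85 ± 1.49 to 2.58 ± 0.252 FPKM. MT1G, a member of a family of close paralogs, fell to 0.274 of its DMSO level. All 12 rises and all 12 falls were called with the GC trend removed and in limma-voom on recovered fragments. The calls of 9 of the 12 rises and of all 12 falls held whichever library was left out.

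**Figure D3:**
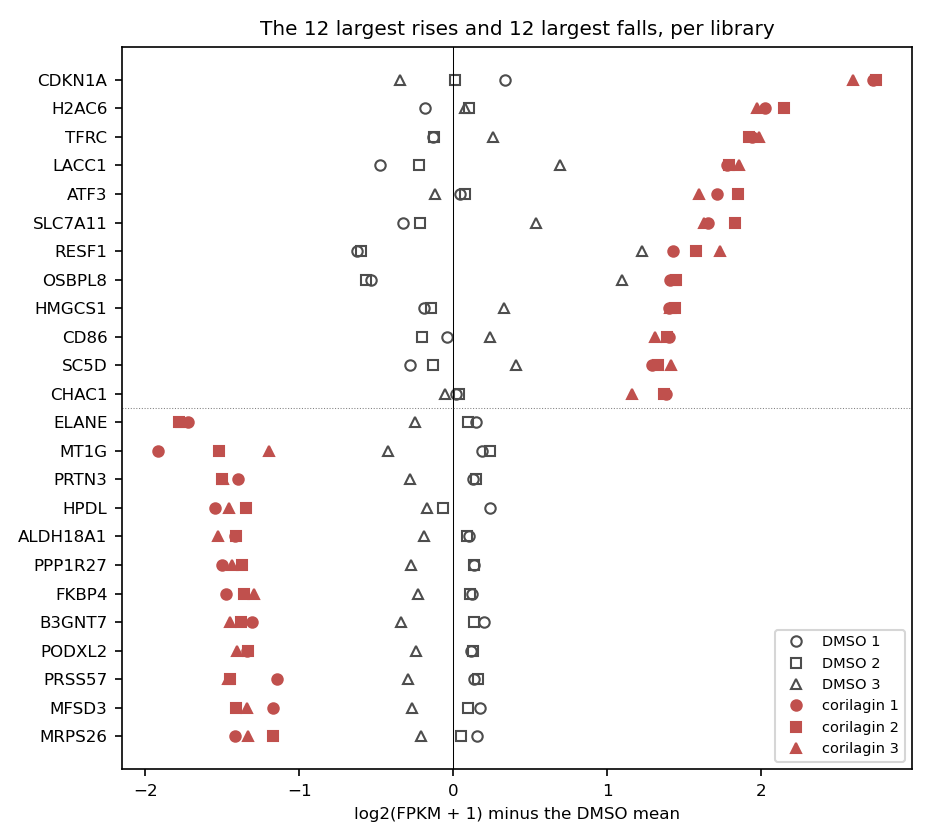
Log2(FPKM + 1) of each library minus the DMSO mean for the 12 largest rises (top) and the 12 largest falls (bottom), with DMSO libraries as open symbols and corilagin libraries filled. CDKN1A lies at the top with a mean log2 fold change of 2.69, ELANE has the largest fall at -1.76, and DMSO replicate 3 of RESF1 and OSBPL8 lies near the corilagin libraries.

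Of 41 gene lists fixed before the data were examined, 36 had at least 5 tested members, and limma's camera test with a preset correlation called 10 higher and 7 lower. No list was called with an estimated correlation, although 8 had an unadjusted p under 0.05, and fry, which asks whether a list's genes move one way on balance, called 18. With the GC trend removed, camera called 10 higher and 6 lower, 15 of them in the direction of the values as deposited, and 1 list (MYC and ribosome biogenesis) also passed with an estimated correlation. Other splits of the 6 libraries, which still hold part of the treatment difference, gave up to 16 called lists. Counts of members are given beside the called lists.

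Sterol synthesis genes rose together. In the list of cholesterol synthesis genes and SREBP2 targets, 17 of 23 members were higher, 1 lower and 5 did not pass (19 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.78. The camera adjusted p was 1.61e-08, and the adjusted p = 0.106 with an estimated correlation. HMGCS1, which makes the precursor of mevalonate, rose 2.70-fold from 25.2 ± 5.47 to 68.0 ± 1.06 FPKM, and SC5D, a late sterol desaturase, rose 2.98-fold, while PMVK, phosphomevalonate kinase, fell to 0.631 of DMSO. The median was 0.74 with the GC trend removed, where 22 members were higher, and 0.78 against DMSO replicate 3 alone. Of 13 fatty acid synthesis genes and SREBP1 targets, 7 were higher and none lower (7 and 0 adjusted over the list alone; camera adjusted p = 0.0171, and adjusted p = 0.283 with an estimated correlation). ACSL3 and ACSS2, both acyl-CoA synthetases, rose 1.81-fold and 1.80-fold. ACSL3 lay at 14.45 FPKM in DMSO replicate 3 against a corilagin mean of 18.3 FPKM. Its log2 value went from 0.85 to 0.46 with the GC trend removed, while that of ACSS2 went from 0.81 to 0.91. The list's call was lost without DMSO replicate 3 (adjusted p = 0.180). After GC trend removal 9 of its members were higher. LXR targets were not called, with 2 of 8 higher (SCD and PLTP; 2 adjusted over the list alone; 4 with the GC trend removed; camera adjusted p = 0.549).

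Stress-response genes were higher in several lists. Among integrated stress response genes and ATF4 targets, 15 of 30 were higher and 2 lower (17 and 3 adjusted over the list alone), with a camera adjusted p of 0.000142, and an adjusted p = 0.251 with an estimated correlation. ATF3, SLC7A11 and CHAC1 were among the rises, and the 2 falls were ALDH18A1 and PYCR1, consecutive enzymes of proline synthesis, the latter to 0.586 of DMSO. The median was 0.31 both as deposited and with the GC trend removed. Hypoxia-response genes were higher in 9 of 20 cases and lower in none (10 and 2 adjusted over the list alone; camera adjusted p = 0.00293, and adjusted p = 0.168 with an estimated correlation). DDIT4, an inhibitor of mTORC1, rose 2.50-fold from 18.6 ± 1.10 to 46.6 ± 1.97 FPKM, and BNIP3L, a mitophagy receptor, rose 2.30-fold. DDIT4 is also in the stress-response list, so the lists are not separate evidence. Of the 13 hypoxia genes not shared with the stress-response and glycolysis lists, 5 were higher and none lower. Their unadjusted camera p was 0.0468, or 0.113 with an estimated correlation. The p53 target list had 7 of 24 members higher and 2 lower (9 and 3 adjusted over the list alone; camera adjusted p = 0.0395, and adjusted p = 0.224 with an estimated correlation). RRM2B rose 2.04-fold beside CDKN1A, though DMSO replicate 3 lay at 30.2 FPKM against a corilagin mean of 39.9 FPKM. Its log2 value went from 1.08 to 0.65 with the GC trend removed (limma adjusted p = 0.00134). AEN and PHLDA3 fell to 0.654 and 0.638 of DMSO. The PHLDA3 call ended with the GC trend removed (log2 value -0.38 as deposited and -0.17 with the trend removed, adjusted p = 0.113). The p53 call was lost without DMSO replicate 3 (adjusted p = 0.198) and on rescaling to equal library sums (adjusted p = 0.0513). After removal of the GC trend, 19 stress-response genes were higher and 3 lower, 14 hypoxia genes were higher and 2 lower, and 13 p53 targets were higher and 4 lower. The lists of endoplasmic reticulum chaperones (7 of 24 higher, 2 lower; 8 and 3 adjusted over the list alone; 9 and 4 with the GC trend removed; camera adjusted p = 0.113) and NRF2 targets (3 of 16 higher, 2 lower; 3 and 2 adjusted over the list alone; 6 and 4 with the GC trend removed; camera adjusted p = 0.596) were not called. DNAJB9 rose 2.30-fold and SDF2L1 fell to 0.642 of DMSO in the former, and in the latter SLC7A11, ME1 and GCLC rose, ME1 without a call once the GC trend was removed (log2 value 0.86 as deposited and 0.43 with the trend removed, adjusted p = 0.0636).

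Interferon-stimulated genes were higher in 14 of 26 cases and lower in none (19 and 1 adjusted over the list alone; camera adjusted p = 6.42e-05, and adjusted p = 0.168 with an estimated correlation). IFIT2 and IFIT3, antiviral RNA-binding proteins, rose 4.80-fold and 4.54-fold in FPKM, to 1.71 ± 0.278 and 1.73 ± 0.371 FPKM, although their changes on the log2(FPKM + 1) scale were 1.0 and 0.98 because of their low levels. The median of the list was 0.43, against 0.33 with the GC trend removed, and the call was lost among the 10 members with a mean of at least 5 FPKM, 3 of them higher (adjusted p = 0.131). Aryl hydrocarbon receptor targets were higher in 4 of 9 cases (CYP1B1, TIPARP, NFE2L2 and CYP1A1) and lower in none (6 and 0 adjusted over the list alone; camera adjusted p = 0.00657, and adjusted p = 0.168 with an estimated correlation). CYP1B1, a xenobiotic-metabolising P450 enzyme, rose 3.20-fold, and TIPARP, a repressor of the receptor, 2.32-fold. In the TGF-beta and SMAD list, 6 of 14 were higher and none lower (7 and 0 adjusted over the list alone; camera adjusted p = 0.0145, and adjusted p = 0.185 with an estimated correlation). Its examples TGFBR1 and SKIL, a receptor and a negative regulator of the pathway, rose 2.05-fold and 2.29-fold. DMSO replicate 3 lay at 25.1 and 4.1 FPKM, against corilagin means of 37.4 and 6.56 FPKM. With the GC trend removed, the log2 value went from 1.04 to 0.62 for TGFBR1 and from 1.0 to 0.47 for SKIL. The call of the TGF-beta list was lost without DMSO replicate 3 (adjusted p = 0.198). Once the GC trend was removed, 17 interferon-stimulated genes were higher and 2 lower, and 7 aryl hydrocarbon receptor targets and 9 TGF-beta genes were higher with none lower. Antigen presentation genes were called lower (camera adjusted p = 0.0150, and adjusted p = 0.599 with an estimated correlation) with 3 of 19 lower (TAP1, HLA-DRA and PSMB8) and 1 higher, or 1 and 1 adjusted over the list alone. The list was not called with the GC trend removed (2 higher, 4 lower, adjusted p = 0.341), and the rise of its member B2M, 1.33-fold as deposited, shrank to a log2 value of 0.03.

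MYC and ribosome biogenesis genes fell together, with 29 of 39 members lower, none higher and 10 not passing (30 lower and 0 higher adjusted over the list alone), and a median log2 fold change of -0.57. The camera adjusted p was 1.03e-12, and the adjusted p = 0.106 with an estimated correlation. With the GC trend removed 35 members were lower, the median was -0.52, and the adjusted p = 0.0222 with an estimated correlation. MYC fell from 65.1 ± 5.44 to 26.1 ± 1.93 FPKM, or 0.401 of DMSO, and SRM, spermidine synthase, to 0.426. Nuclear-encoded oxidative phosphorylation genes were lower in 22 of 40 cases and higher in none (24 and 0 adjusted over the list alone; camera adjusted p = 9.49e-06, and adjusted p = 0.168 with an estimated correlation). ATP5MC1, a subunit of ATP synthase, and CYC1, cytochrome c1, fell to 0.557 and 0.580 of DMSO. Heat shock genes were lower in 9 of 18 cases and higher in none (9 and 0 adjusted over the list alone; camera adjusted p = 0.000886, and adjusted p = 0.168 with an estimated correlation). The HSP90 co-chaperones FKBP4 and AHSA1 fell to 0.366 and 0.550 of DMSO, and the list's call was lost without DMSO replicate 3 (adjusted p = 0.0619). With the GC trend removed, 29 oxidative phosphorylation genes were lower and 1 higher, and 13 heat shock genes were lower and none higher.

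Ribosomal protein genes had 6 of 67 members lower and none higher (0 and 0 adjusted over the list alone; camera adjusted p = 0.00657, and adjusted p = 0.599 with an estimated correlation). RPL8 and RPS2 fell to 0.696 and 0.701 of DMSO. The list median was -0.15, but -0.02 against DMSO replicate 3 alone, and the call was lost with quantile normalization (camera adjusted p = 0.779). Of the 13 mitochondrially encoded mRNAs, 4 were lower (MT-ATP8, MT-ND5, MT-ND6 and MT-CO3) and none higher (6 and 0 adjusted over the list alone; camera adjusted p = 0.000366, and adjusted p = 0.599 with an estimated correlation). MT-ND5 fell from 1723 ± 308 to 1097 ± 95.3 FPKM. The median over the 13 mRNAs was -0.57 against DMSO replicates 1 and 2 and -0.08 against DMSO replicate 3, and the call was lost with quantile normalization (adjusted p = 0.276). Once the GC trend was removed, 18 ribosomal protein genes were lower and 1 higher, and 9 mitochondrially encoded mRNAs were lower.

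Genes of granulocyte precursors fell, with 8 of 15 lower and 1 higher (9 and 1 adjusted over the list alone; camera adjusted p = 0.000633, and adjusted p = 0.283 with an estimated correlation). MS4A3, a marker of granulocyte-monocyte progenitors, fell to 0.126 of DMSO, from 5.89 ± 0.870 to 0.741 ± 0.189 FPKM, next to ELANE, while CXCR2, a receptor of mature neutrophils, rose 1.55-fold. The granulocyte list had 10 lower and 4 higher members with the GC trend removed. Monocyte and macrophage genes were not called (7 of 23 higher, 3 lower; 11 and 5 adjusted over the list alone; 11 and 7 with the GC trend removed; camera adjusted p = 0.371). CD86 and NCF1, an oxidase subunit with near-identical pseudogenes, rose 2.95-fold and 2.38-fold, whereas LYZ and S100A9, abundant products of myeloid cells, fell to 0.625 and 0.652 of DMSO, and IRF8 also fell. In the list of the KMT2A fusion program, 4 of 17 were higher (FLT3, PBX3, MEIS1 and LAPTM4B) and none lower (4 and 0 adjusted over the list alone; camera adjusted p = 0.0395, and adjusted p = 0.599 with an estimated correlation). FLT3 rose 1.43-fold, from 217 ± 39.4 to 311 ± 6.30 FPKM, and this list was not called with the GC trend removed (8 higher, 2 lower, adjusted p = 0.0914), nor without corilagin replicate 2 or 3 (adjusted p = 0.0572 and 0.0513), without DMSO replicate 1 or 2 (0.0859 and 0.0931), with a replicate block (0.0539), with median-of-ratios scaling (0.0564), with the GC and length trends removed (0.131) or without the first 2 DMSO libraries (0.7504). The FLT3, STAT5 and ERK output list had 4 of 21 higher (DUSP5, PHLDA1, FLT3 and ETV5) and 5 lower (EGR1, OSM, CCND3, PIM3 and SOCS3; 5 and 6 adjusted over the list alone; camera adjusted p = 0.800), against 10 higher and 4 lower with the GC trend removed. DUSP5, an ERK phosphatase, rose 2.40-fold, and EGR1 fell to 0.532 of DMSO.

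**Figure D4:**
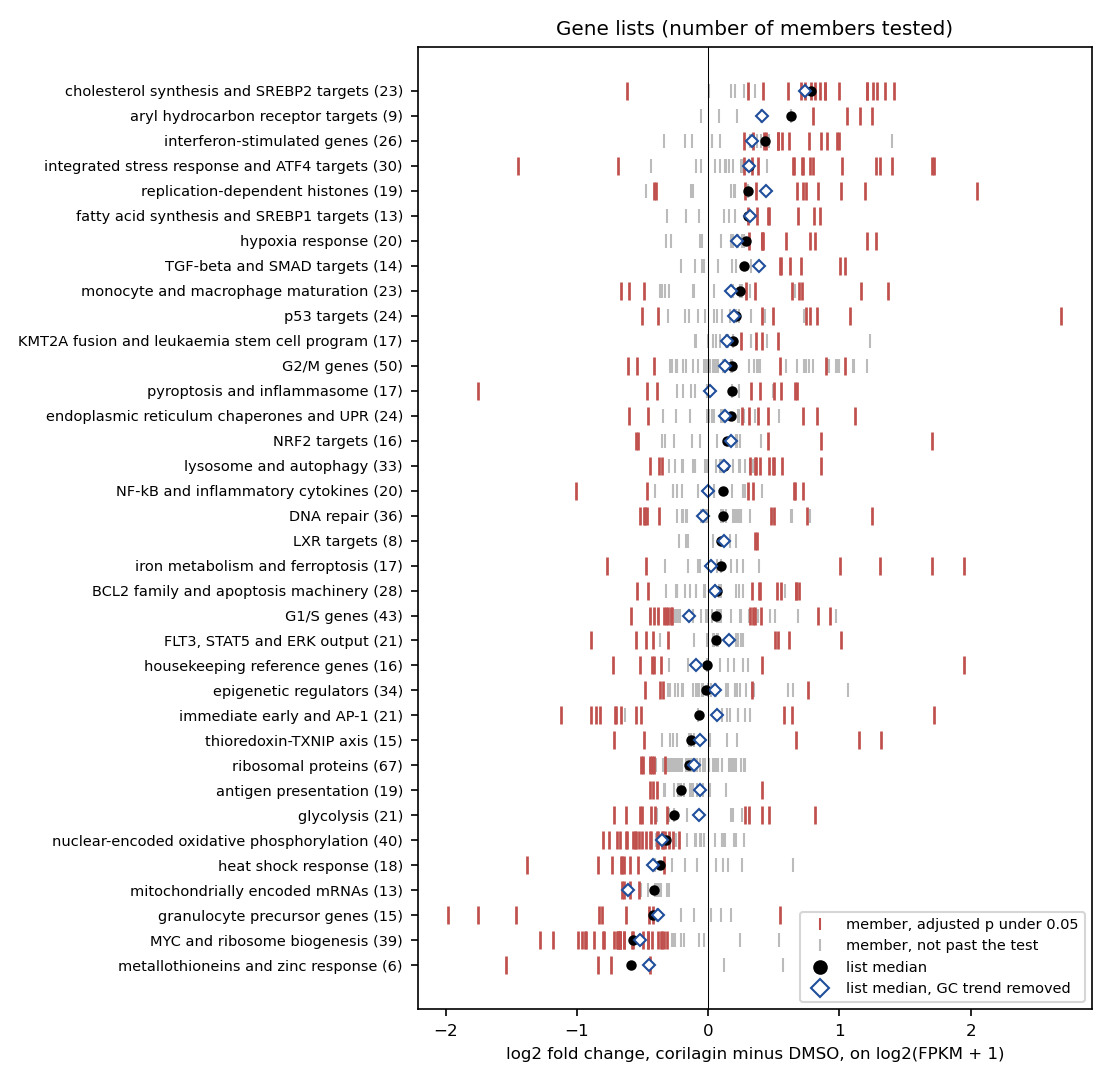
Log2 fold change (corilagin minus DMSO, on log2(FPKM + 1)) of every tested member of the 36 gene lists with at least 5 tested members, in red where the adjusted p is under 0.05 and grey otherwise, with the list median as a filled circle and the median after GC trend removal as an open diamond. Cholesterol synthesis lies at a median of 0.78 and MYC and ribosome biogenesis at -0.57.

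Cell cycle lists were mixed. Of 43 G1/S genes, 6 were higher and 9 lower (11 and 15 adjusted over the list alone; camera adjusted p = 0.680), and with the GC trend removed 9 were higher and 20 lower, with the median moving from 0.06 to -0.15. CCNE2 rose 1.91-fold, with DMSO replicate 3 at 11.3 FPKM against a corilagin mean of 13.7 FPKM. Its log2 value went from 0.93 to 0.45 with the GC trend removed. UNG and MCM7 fell to 0.649 and 0.729 of DMSO. Among 50 G2/M genes, 3 were higher (CKAP2L, NDC80 and KIF4A) and 3 lower (CDC20, PLK1 and CCNB1; 1 and 1 adjusted over the list alone; camera adjusted p = 0.124), against 19 higher and 11 lower with the GC trend removed. The G2/M list was called higher with quantile normalization (9 higher, 3 lower, adjusted p = 0.00817) and without DMSO replicate 3 (31 higher, 13 lower, adjusted p = 0.0214), and with a replicate block 18 were higher and 3 lower (adjusted p = 0.0517). PLK1, a mitotic kinase, fell to 0.669 of DMSO. Replication-dependent histone genes, many of which lack poly(A) tails and have close copies, were higher in 9 of 19 cases and lower in 2 (10 and 2 adjusted over the list alone; camera adjusted p = 0.0113, and adjusted p = 0.224 with an estimated correlation). H2BC11 rose 2.72-fold and H1-2 fell to 0.747 of DMSO, and the call was lost without DMSO replicate 3 (adjusted p = 0.266). After GC trend removal 11 histone genes were higher and 2 lower. DNA repair genes were higher in 4 of 36 cases (BRCA2, BARD1, FANCI and XRCC1) and lower in 5 (XRCC6, LIG3, POLD1, ERCC2 and PARP1; 4 and 5 adjusted over the list alone; camera adjusted p = 0.787), against 8 higher and 9 lower with the GC trend removed, where the median moved from 0.11 to -0.04.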

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

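Settings that removed a GC or length trend, left out the first 2 DMSO libraries, or used limma-voom were chosen after seeing the data. TXNIP stayed higher and past the test under every alternative (log2 fold change 0.87 to 1.33), and GSDME never passed it (-0.28 to -0.08), with no value at a mean of at least 5 FPKM, where the gene is filtered out. As deposited, 1171 genes were higher and 1331 lower. Removing the GC trend gave 2200 and 2348, the GC and length trends 2174 and 2376, the GC trend with a replicate block 2154 and 2266, and the GC trend without the third DMSO library 3096 and 3279. Leaving out the first 2 DMSO libraries, with the remaining one assumed to vary like the corilagin libraries, gave 1916 higher, and with the GC trend removed 1989 and 2048. The smaller set at a mean of at least 5 FPKM gave 713 higher. A log2 fold change of at least 1 left 76 and 42, and an adjusted p under 0.01 left 189 and 286. Leaving out single libraries gave 131 to 4030 higher and 176 to 3597 lower genes, with 369 and 483 without DMSO replicate 1, 223 and 298 without DMSO replicate 2, and the top of each range without DMSO replicate 3. The fit without DMSO replicate 3 aligns the GC difference between libraries with treatment. The cause of these moves was not tested, except where fewer genes or samples entered by construction.

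Called gene lists numbered 0 with an estimated correlation in place of 17 with the preset one, and 12 to 18 under every other alternative taken alone (13 to 17 without single libraries, 18 with fry). With the GC trend also removed, an estimated correlation gave 1 list and fry 26. Of the 17 lists, 7 kept call and direction under all 22 settings of the FPKM values, namely cholesterol synthesis, integrated stress response, hypoxia, MYC and ribosome biogenesis, oxidative phosphorylation, granulocyte precursors and aryl hydrocarbon receptor targets. At a mean of at least 5 FPKM, where fewer genes enter, the calls of interferon-stimulated genes, p53 targets, TGF-beta targets and antigen presentation were lost (adjusted p = 0.131, 0.149, 0.0856 and 0.198), and that of histones without a filter (0.0664). Lists not called as deposited were called higher for endoplasmic reticulum chaperones with quantile normalization (0.0228) and NRF2 targets without the first 2 DMSO libraries (0.0145), and lower for metallothioneins without a filter (0.0496) and on rescaling to equal library sums (0.0425). Of 131 other named genes, 123 were counted as unchanged with the GC trend removed, 6 lost their call, 1 gained one and 1 reversed. A reversal here is a change of sign with a call in at least 1 of the 2 fits compared. Sign changes without a call in either fit were counted as unchanged, as for EPOR (log2 value -0.17 to 0.06), NKG7 (-0.17 to 0.002) and GSDMB (-0.009 to 0.01). Without a filter on low values 35 of 131 lost their call, and without single corilagin libraries 71 to 76. Reversals were TXN (-0.33 with the GC trend removed, -0.33 with a replicate block added and -0.48 without the third DMSO library), B2M (-0.10) and CASP8 (-0.14) with the GC trend removed and without the third DMSO library, and H2AC20 (0.0155 with GC and length trends removed), and the cause was not tested.

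Whether replicate numbers pair the libraries could not be told. Deviations of same-numbered libraries correlated at 0.28, 0.08 and 0.34, and at 0.07, 0.03 and 0.1 with the GC trend removed. As deposited, corilagin replicate 1 correlated equally with DMSO replicates 1 and 2, and not every library correlated best with its own number. Deviations within a group cancel out, so these correlations depend on each other and cannot decide the question. With the number as a replicate block 1547 genes were higher and 1330 lower, and 16 lists were called. The planned count test was not run because the table holds FPKM, although limma-voom was run on the recovered fragments.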

Other observations

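The tests of GC content behind the third DMSO library, of GC content and of treatment behind the mitochondrial mRNAs, and of the splits with the GC trend removed were chosen only after their results had been seen.

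Further lists fixed in advance described inflammation, metabolism and metal handling, and none of them was called by camera as deposited. In the NF-kB and inflammatory cytokine list, 5 of 20 members were higher (EBI3, IL1B, CCL5, IL23A and TRAF1) and 2 lower (TNF and RELB; 5 and 3 adjusted over the list alone; 8 and 6 with the GC trend removed; camera adjusted p = 0.680). TNF fell from 113 ± 8.35 to 55.4 ± 3.44 FPKM (SD, n = 3 per group), or 0.492 of DMSO, while IL1B rose 1.72-fold. Immediate early genes were higher in 3 of 21 cases (ATF3, KLF6 and JUN) and lower in 9 (3 and 10 adjusted over the list alone; camera adjusted p = 0.276), against 9 higher and 9 lower with the GC trend removed, where the median turned from -0.07 to 0.07. DUSP2 and EGR1 fell to 0.420 and 0.532 of DMSO, and KLF6 rose 1.70-fold. Glycolysis genes were higher in 5 of 21 cases (ALDOC, ENO2, SLC2A3, PFKFB3 and HK2) and lower in 7 (6 and 9 adjusted over the list alone; 7 and 9 with the GC trend removed; camera adjusted p = 0.382). The isoenzymes differed, with ALDOC and ENO2 rising 1.84-fold and 1.55-fold and the far more abundant ENO1 falling to 0.640 of DMSO, from 460 ± 75.9 to 295 ± 8.70 FPKM. Of 6 metallothioneins and zinc-response genes, 4 were lower (MT1G, MT2A, MT1E and MT1F) and none higher (4 lower and 1 higher adjusted over the list alone; 4 and 0 with the GC trend removed; camera adjusted p = 0.0913). Iron and ferroptosis genes were higher in 4 of 17 cases (TFRC, SLC7A11, CHAC1 and ACSL4) and lower in 2 (STEAP3, at 0.473 of DMSO, and GPX4, at 0.712; 4 and 2 adjusted over the list alone; 7 and 2 with the GC trend removed; camera adjusted p = 0.317). Lysosome and autophagy genes were higher in 9 of 33 cases and lower in 3 (CTSZ, TFEB and GLA; 11 and 3 adjusted over the list alone; camera adjusted p = 0.168). With the GC trend removed this list was called higher (13 higher, 2 lower, adjusted p = 0.0292, but 0.557 with an estimated correlation), and TFEB lost its call (log2 value -0.38 as deposited and -0.16 with the trend removed, adjusted p = 0.0649).

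Epigenetic regulators were higher in 2 of 34 cases (SIRT1 and EZH2) and lower in 3 (MEN1, HDAC3 and KDM1A), with 0 and 0 adjusted over the list alone, and 8 and 6 with the GC trend removed (camera adjusted p = 0.836, median -0.02, mean 0.06). Genes used as housekeeping references were not called (camera adjusted p = 0.680). Their median of -0.01 became 0.11 on rescaling to equal library sums and 0.10 with quantile normalization. Markers of other cell types were mostly below 1 FPKM. Only 1 of 15 T and NK cell markers was tested (NKG7, 48.3 ± 2.79 FPKM after corilagin and 55.1 ± 10.2 FPKM in DMSO, adjusted p = 0.352). Of 3 tested B cell markers, IGLL1, the surrogate light chain of B cell precursors, fell from 4.11 ± 0.909 to 0.304 ± 0.0860 FPKM, or 0.0740 of DMSO. None of 3 erythroid and megakaryocyte markers passed (EPOR and GP1BA, adjusted p of 0.360 and 0.435). Of 3 fibroblast and endothelial markers, PECAM1 rose 1.29-fold and EGFL7 fell to 0.622 of DMSO, and of 4 epithelial markers CLDN7 rose 1.5-fold. Over each of these 5 short lists alone, the counts of higher and lower members were 0 and 0 for T and NK cells, 0 and 1 for B cells, 0 and 0 for erythroid cells, 1 and 1 for fibroblasts and endothelium, and 2 and 0 for epithelium. In that order they were 0 and 0, 0 and 1, 2 and 0, 2 and 1, and 2 and 0 with the GC trend removed, by the adjustment over all tested genes.

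The library labelled DMSO replicate 3 stood apart from the other DMSO libraries, at -5.8 on the first principal component (83.1% of the variance) against 32.8 and 29.3 for DMSO replicates 1 and 2 and -17.5 to -20.5 for corilagin. A mixture with corilagin-treated material as the whole cause was argued against, since such a mixture would place responding genes at 1 shared position between the groups, whereas the median position in DMSO replicate 3 was 0.85 for 379 genes under 45% GC and 0.41 for 87 genes of 50% GC or more, a difference of 0.44 (bootstrap interval 0.39 to 0.50). A smooth trend with GC content as the whole cause was also argued against. With that trend removed, the median absolute log2 difference of DMSO replicate 3 from its closer DMSO library fell from 0.280 to 0.120, still 2.0 times that of the widest other pair within a group (4.17 times as deposited), and on the first principal component it lay at 7.9 against 18.7 and 18.1 for the other DMSO libraries. Whether a smaller share of treated material was also present cannot be told apart, as 20.2% of 104 responding genes lay at or beyond the other DMSO libraries with the GC trend removed (exact interval 13 to 29.2%), around the bound of 20% set in advance, with a median position of 0.14. The bootstrap and exact intervals treat the genes of 1 library as independent, which they are not, so neither measures the spread between libraries. The labels give no preparation batch, so a batch shared by DMSO replicate 3 and the corilagin libraries, or different cultures, stays open and was not tested.

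Mitochondrially encoded mRNAs took 3.66 ± 0.190% of fragments after corilagin and 4.92 ± 1.0% in DMSO (SD, n = 3 per group), with 5.87, 5.03 and 3.85% in DMSO replicates 1, 2 and 3 (Wilson interval 3.85 to 3.86% for the last, counting error only). The GC trend fitted over all tested genes was argued against as the whole cause. The median log2 change of the 13 mRNAs was -0.61 with it removed and -0.41 as deposited. Their median GC content was 44.3%. In the eighth of 42.8 to 45.7% GC, corilagin libraries lay at 0.08 to 0.11 and DMSO replicates 1 and 2 at -0.20 and -0.15. The trend there runs against the fall, so its removal was bound to deepen it. Whether mitochondrial mRNAs follow that trend was not tested. A response to corilagin alone cannot be told apart from a difference among the DMSO libraries, since the median difference from DMSO replicate 3 lay 0.49 above that from DMSO replicates 1 and 2 and 1 library decides.

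A shortage of available iron is a candidate explanation for the higher TFRC and hypoxia-response genes, since the TFRC mRNA is stabilised and prolyl hydroxylases lose activity when iron is scarce. SLC11A2, an iron transporter whose mRNA also carries an iron-responsive element, was at 5.87 ± 0.259 FPKM after corilagin and 5.43 ± 0.566 FPKM in DMSO, with a log2 fold change of 0.10 (SE 0.0936, adjusted p = 0.419) that turned to -0.04 with the GC trend removed (adjusted p = 0.620). The 13 hypoxia genes not shared with the stress-response and glycolysis lists had 5 higher and none lower members, with a camera p of 0.0468 and a p of 0.113 with an estimated correlation. These values do not decide between an iron shortage and other routes to the same genes, because SLC11A2 passed the test in neither direction, and only some of its transcript forms carry the element.

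With 3 libraries per group there are 10 splits, too few for a share under 0.05. The real split was the 1 of 10 with the most called genes, 2502 as deposited against 0 for the highest other split, and 4548 against 0 with the GC trend removed. At an unadjusted p under 0.05, limma had 4464 genes in the real split as deposited against at most 1475 in another, and 5374 against at most 508 with the GC trend removed. For gene lists the real split was again 1 of 10, with 17 called lists against 16 for the highest other. Every other split mixes the treatments unevenly, so part of the treatment difference stays in it and the rest adds to the spread. These counts therefore do not show how many genes or lists would be called without a treatment difference. The number of lists called by camera with the preset correlation also does not set the real grouping apart.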
